A study of Sus scrofa with 12 samples.

How the data were processed

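Gene expression was measured on Affymetrix porcine 3' IVT arrays in valvular interstitial cells, the fibroblast-like cells that populate the heart valve leaflet, isolated from adult pig aortic valves by collagenase II digestion. The 12 arrays form 4 groups of 3 biological replicates. P0 cells were taken directly after isolation. P2 cells had been passaged 2 times on tissue culture plastic and were kept in low serum, either untreated or with porcine TGF-β1 at 5 ng/ml for 8 h or 24 h before collection on day 3 of culture.

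The deposited values are log2 expression values per probe set, 1 column per array. The submitters' processing notes name GCRMA, with no version. How the arrays were normalised beyond that, the scan dates and any processing batches are not given in the sources used here. The values ran from 1.74 to 15.95, and the array medians lay within 0.079 of each other, so the values were used as deposited. The number of arrays per group limits the precision, and the median standard error of a log2 fold change was 0.159.

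The table held 23999 probe sets. The 64 reporter control probe sets were left out. Of all probe sets, 10069 carried 1 gene symbol, 198 carried several and 13732 carried none. A probe set was tested if its log2 value was over 4 in at least 3 of the 12 arrays, which left 17638, of which 8466 had 1 symbol. Reporter control values had a median of 3.07, and 86.7% of them were under log2 4. Where a group mean lay under their 95th percentile of 4.58, the fold is given as a lower bound, from that level to the other group's mean, without an error. A gene was represented by its probe set with exactly 1 symbol and the highest mean over all arrays, which gave 6014 genes, of which 1782 had more than 1 probe set. The raw image files were not used here.

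The 4 group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 3.745 prior degrees of freedom). The 4 comparisons were P2 untreated against P0, TGF-β1 at 8 h against untreated, TGF-β1 at 24 h against untreated, and 24 h against 8 h. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the probe sets tested in each comparison, and a probe set was called at an adjusted p under 0.05. Errors given with log2 fold changes are standard errors from limma, with 3 arrays in each group.

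Gene lists were compared with all other genes by camera from limma, with a preset correlation of 0.01, and adjusted over the lists with at least 5 measured members. The lists covered contractile and cytoskeletal genes, fibrillar collagen and its processing, basement membrane, elastic fibre, proteoglycan and hyaluronan, and matricellular proteins. Others covered TGF-β induced targets, TGF-β repressed targets, cell cycle, matrix proteases, osteogenic and chondrogenic genes, cytokines and NF-kB, immediate-early and heat shock genes, and interferon response. The remaining ones covered cholesterol biosynthesis, the unfolded protein response, PI3K and AKT signalling, valve transcription factors, glycolysis and hypoxia, oxidative phosphorylation, and complement with other secreted factors of resting fibroblasts. Marker lists for endothelial cells, macrophages, lymphocytes, erythrocytes, muscle and adipocytes stood for other cells a valve digest could hold. The fry test, camera with a correlation estimated for each list, and 10000 random lists matched on mean expression were run beside it. The correlations were estimated in the fit of group means alone, which leaves out replicate number.

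The lists, the groups, the comparisons, the tests and the rule for naming genes were fixed before the data were examined. The rule took, for each comparison, the 8 largest rises and the 8 largest falls among called genes with 1 symbol whose groups did not overlap. It added a fixed panel (among its genes ACTA2, TAGLN, CNN1, COL1A1, COL3A1, FN1, CCN2, SMAD7, TGFBI, LOX, IL6, MKI67 or TOP2A, PECAM1 and CD68), and from each list described up to 4 called members with the largest change, or the 2 smallest p-values where none was called. COL1A1, CCN2, SMAD7, TGFBI, MKI67 and CD68 were not on a probe set with a single listed symbol.

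The pipeline was tested on simulated data with the same number of probe sets, of which 200 were changed. A log2 change of 1 was recovered for 73.1% to 79.1% of changed probe sets depending on the comparison, with 4 to 8 false calls, and a change of 0.5 for 11.9% to 19.4%. A simulated shift of 0.5 in the cell cycle list was called in all 4 comparisons, with 0 other lists called. Simulated probe sets and arrays were drawn independently, so false list calls among correlated genes were not tested. In the real data 59.4% of probe sets were called in culture, and P2 arrays were linked by replicate number. The simulated recovery rates therefore need not hold for the real comparisons. The estimated correlation of the real cell cycle list was 0.483. Alternatives tried were no filter, a stricter filter at log2 6, a floor at log2 4, quantile normalization on top, arrays centred on their median, a fit of the 2 groups alone, eBayes with trend and robust settings, array weights, replicate number as a block, a test against a 1.5-fold change, and each array left out in turn. Lists were also tested with all probe sets of each gene. A block fit of the 9 P2 arrays alone, a fit without the P2 arrays numbered 3, and a comparison of responses that share no arrays were added after seeing the data.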

Results

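Expression was profiled in 12 arrays of porcine aortic valvular interstitial cells: freshly isolated cells (P0), untreated cells passaged 2 times on plastic (P2), and P2 cells given TGF-β1, a cytokine known to turn fibroblasts into matrix-producing myofibroblasts, for 8 h or 24 h. Each group held 3 biological replicates. Between 16564 and 17247 probe sets per array lay over log2 4. Correlation between arrays of the same group ran from 0.982 to 0.994, while P0 arrays correlated with P2 arrays at a median of 0.866. The first principal component separated P0 from all P2 arrays and carried 79.6% of the variance. The second carried 6.30% and the third 4.94%.

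P2 arrays with the same replicate number resembled each other. After group means were removed, same-number arrays of different P2 groups correlated at 0.348 to 0.679 over 9 pairs, against at most 0.0796 for different numbers. P0 arrays showed no such link, with same-number correlations from -0.0916 to 0.0158. The P2 arrays numbered 3 also differed in endothelial markers, shown in the plot of endothelial genes per array. CDH5, the cadherin of endothelial junctions, read 9.96 and 10.79 in untreated replicates 1 and 2 but 6.72 in replicate 3, with a like gap at 8 h and at 24 h. PECAM1, an endothelial adhesion molecule, read 10.54, 10.93 and 8.67 in the same 3 untreated arrays.

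**Figure D1:**
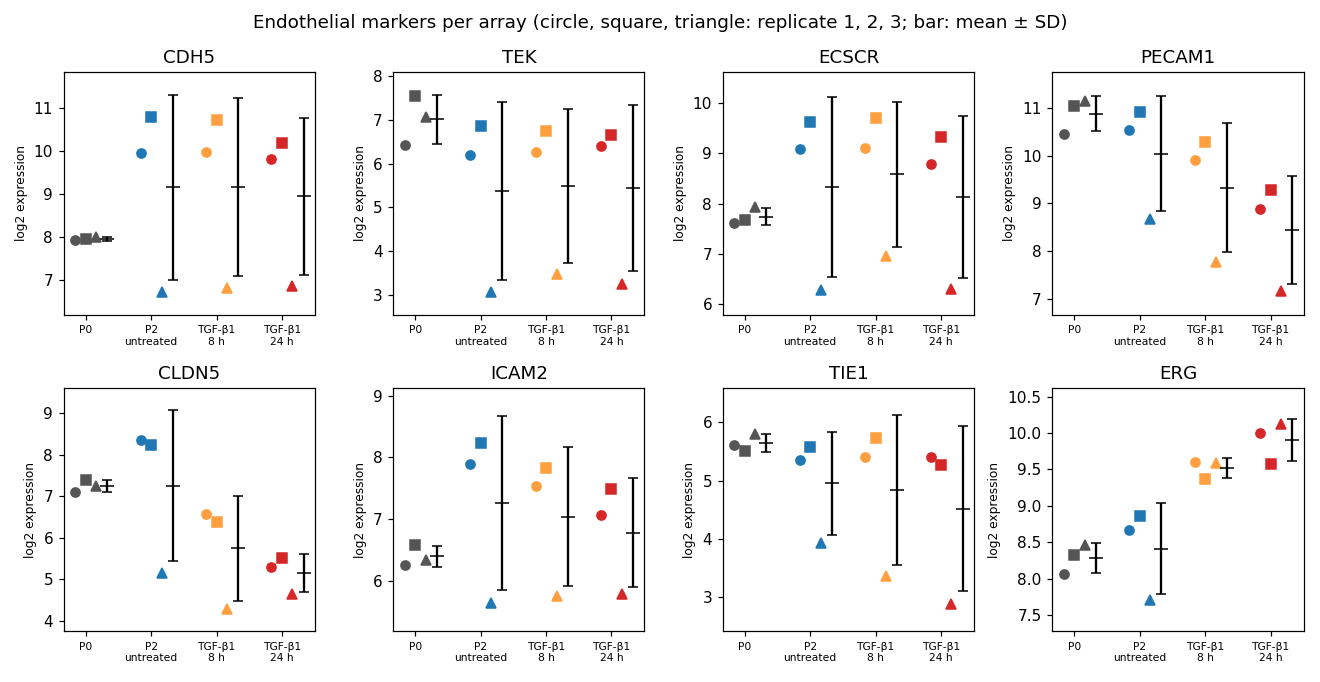
Log2 expression of 8 endothelial genes in each of the 12 arrays, by group, with the mean and SD and a symbol for each replicate number. CDH5 lay at 6.72 in untreated replicate 3 and at 9.96 and 10.79 in the other untreated arrays.

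The first comparison asked what passaging and culture on plastic changed against freshly isolated cells. Cultured cells carried far more contractile, proliferative and sterol-synthesis transcripts, and far fewer stress-response, cytokine and resting-fibroblast transcripts. With an estimated correlation only the immediate-early (adjusted p = 0.0147) and cytokine lists (0.0136) held, while the contractile (0.118), cell cycle (0.202), cholesterol (0.0819) and secreted factor lists (0.0870) did not. ACTA2, the smooth muscle actin of myofibroblasts, rose 7.42-fold (log2 fold change 2.89 ± 0.159 SE, adjusted p = 3.04e-08, 3 against 3 arrays). SCARA5, a scavenger receptor of resting fibroblasts, fell at least 471-fold (adjusted p = 3.61e-10) to a mean of 3.70, inside the range of the reporter controls. RRM2, the ribonucleotide reductase subunit made in S phase, rose at least 67.7-fold, and FOS, an immediate-early transcription factor, fell 128-fold (-7.00 ± 0.269).

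By the deposited values the other largest rises were AKR1CL1, an aldo-keto reductase (log2 fold change 7.18 ± 0.217), PCLAF, a factor of the replication clamp (64.0-fold, SE 0.176 on the log2 scale), BASP1 (at least 25.1-fold), VGLL3, a cofactor of TEAD transcription factors (5.45 ± 0.280), and ITGA8, the integrin α8 subunit (at least 40.1-fold). DLGAP5 (at least 33.3-fold) and SKA1 (at least 12.8-fold), both of the mitotic spindle, completed this set. The other largest falls by those values were COMP, cartilage oligomeric matrix protein (-7.88 ± 0.882), FMO1 (at least 68-fold), the chemokine CCL4 (-7.72 ± 0.154), the water channel AQP3 (at least 187-fold), the complement regulator C4BPA (-7.47 ± 0.240) and CILP, a cartilage-type matrix protein (at least 71.7-fold). In each of these genes the P0 and P2 arrays did not overlap, but the order among those given as bounds is set by background.

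Of 23 measured contractile and cytoskeletal genes, 19 rose and 2 fell, with a median log2 fold change of 1.45 (camera adjusted p = 0.000127; adjusted p = 0.118 with an estimated correlation). FHL2 (3.25 ± 0.135), TPM1 (3.14 ± 0.144), TPM2 (3.12 ± 0.198) and CNN2 (2.94 ± 0.166) changed most, and CNN1 (1.42 ± 0.125) and TAGLN (0.99 ± 0.136) also rose. The 2 that fell, named after their values were seen, were ACTG2, the enteric smooth muscle actin (-1.90), and TAGLN2 (-0.68). All but 1 of 28 cell cycle genes rose, with a median of 3.25 (adjusted p = 5.7e-09; adjusted p = 0.202 with an estimated correlation). Examples were CCNB1 (5.01 ± 0.170), TOP2A (4.91 ± 0.198) and CCNB2 (4.72 ± 0.188), all active in G2 and mitosis. All 12 cholesterol biosynthesis genes rose, with a median of 2.28 (adjusted p = 2.5e-05; adjusted p = 0.0819 with an estimated correlation), among them FDPS (4.26 ± 0.103) and CYP51 (2.90 ± 0.128).

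Energy metabolism genes moved in the same direction. In the glycolysis and hypoxia list 16 of 22 genes rose and 1 fell (median 1.29, adjusted p = 0.00349; adjusted p = 0.257 with an estimated correlation), with the lactate transporter SLC16A3 up at least 22.8-fold, the glucose transporter SLC2A1 at 3.30 ± 0.171 and LDHA at 3.27 ± 0.125. In the oxidative phosphorylation list 18 of 24 genes rose and 2 fell (median 0.78, adjusted p = 0.0108; adjusted p = 0.293 with an estimated correlation). Among these were MDH2 (1.61 ± 0.146) and CS (1.61 ± 0.0953), while the muscle-type subunit COX7A1 fell (-1.54 ± 0.195). Against random lists matched on expression, the oxidative phosphorylation list had an adjusted p of 0.0676.

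Of 25 immediate-early and heat shock genes 24 fell, with a median of -3.53 (adjusted p = 1.4e-15; adjusted p = 0.0147 with an estimated correlation). Besides FOS the largest changes were in ATF3 (-6.08 ± 0.410), ZFP36 (-5.99 ± 0.134) and NR4A3 (-5.86 ± 0.143). In the cytokine and NF-kB list 22 of 28 genes fell and 3 rose (median -2.12, adjusted p = 2.5e-08; adjusted p = 0.0136 with an estimated correlation). TNF (at least 64.8-fold), CCL3L1 (-6.30 ± 0.124), IL1B (-5.24 ± 0.225) and IL6 (-1.97 ± 0.221) were among those that fell. The 3 that rose, named after their values were seen, were the chemokines AMCF-II (4.61) and CXCL14 (at least 15.6-fold) and the acute-phase gene SAA2 (1.91). Macrophage and monocyte markers lay lower alongside these lists. Of 22 measured markers 18 fell and 1, SLA-DMA, rose by 1.56, seen only afterwards (median -2.20, adjusted p = 4.1e-07; adjusted p = 0.202 with an estimated correlation), with the scavenger receptor CD163 at -5.54 ± 0.478 and SLA-DRA, a class II antigen-presenting molecule, at -4.28 ± 0.428.

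Genes of resting fibroblasts and specialised matrix fell too. In the list of complement and other secreted factors 14 of 17 genes fell and 1 rose (median -2.82, adjusted p = 3.3e-07; adjusted p = 0.0870 with an estimated correlation), including CXCL12 (-5.20 ± 0.188), C3 (-4.77 ± 0.327) and CFD (-4.29 ± 0.297). The 1 that rose was IGF1 (2.26), named after its value was seen. Of 14 proteoglycan and hyaluronan genes 11 fell and 2 rose (median -1.22, adjusted p = 0.000887; adjusted p = 0.120 with an estimated correlation), among them HAPLN1 (-3.60 ± 0.330), ACAN (-3.25 ± 0.551), HAS3 (at least 7.51-fold) and VCAN (-2.53 ± 0.197). The 2 that rose, named after their values were seen, were the syndecans SDC2 (1.98) and SDC4 (0.87). The 12 matricellular genes split into 8 that fell and 4 that rose (median -0.83, adjusted p = 0.0301; adjusted p = 0.120 with an estimated correlation). TNXB (-5.13 ± 0.190) and DPT (-4.11 ± 0.268) fell, whereas SPP1, osteopontin, rose (2.63 ± 0.259), as did TNC (1.96), THBS1 (0.77) and CYR61 (0.53), the last 3 named after their values were seen. With all probe sets of each gene the matricellular list had an adjusted p of 0.190. Elastic fibre genes fell in 3 of 5 cases, MFAP5 (-3.36 ± 0.148), FBLN1 (-2.95 ± 0.183) and MFAP2 (-1.79 ± 0.435), with a list adjusted p of 0.0347 that became 0.273 with an estimated correlation and 0.0563 with all probe sets.

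TGF-β target genes were lower in cultured cells. Of 16 genes known to be induced by TGF-β 12 fell and 1, TPM1, rose (median -1.36, adjusted p = 0.000162; adjusted p = 0.103 with an estimated correlation). TIMP3 (-3.48 ± 0.569), BHLHE40 (-3.40 ± 0.173) and BAMBI (-2.40 ± 0.180) were among those that fell. Of 8 genes known to be repressed by TGF-β 7 fell as well, and ID3, named afterwards, rose by 0.37 (median -1.62, adjusted p = 0.00229; adjusted p = 0.118 with an estimated correlation), including ID1 (-2.19 ± 0.444) and SMAD3 (-2.16 ± 0.156). Valve and mesenchyme transcription factors fell in 8 of 13 cases and rose in 3 (median -0.97, adjusted p = 0.0156; adjusted p = 0.133 with an estimated correlation and 0.0851 with all probe sets). TCF21 (-3.94 ± 0.316), TBX2 (-3.48 ± 0.255) and HES1 (-3.26 ± 0.315) fell most, while HEY2 (1.87), PRRX1 (1.86) and TWIST2 (1.72), named after their values were seen, rose. Osteogenic and chondrogenic genes fell in 7 of 12 cases and rose in 3 (median -0.77, adjusted p = 0.0489; adjusted p = 0.313 with an estimated correlation), with SOX9 at -1.86 ± 0.207. With group means under the control level raised to it, the osteogenic median was -0.30. That call was lost without untreated replicate 1 (adjusted p = 0.0532) or 2 (0.0718), without P0 replicate 1 (0.0579) or 2 (0.0618), with a replicate block (0.0510), with all probe sets (0.0583, median -0.29) and without the filter (0.108, median -0.08).

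The remaining lists were not called. Fibrillar collagen and processing genes rose in 6 of 19 cases and fell in 3 (adjusted p = 0.788), with LOXL4 at 4.66 ± 0.241 and COL5A3 at -2.82 ± 0.563. Basement membrane genes gave 1 rise, NID2 (1.25 ± 0.231), and 3 falls in 6 (adjusted p = 0.326). Among these LAMC1 fell by 0.51 on the log2 scale on its representative probe set while its other 3 probe sets rose. Matrix proteases and inhibitors gave 4 rises, led by the collagenase MMP1 (at least 16-fold), and 5 falls in 14 (adjusted p = 0.788). Interferon response genes gave 4 rises and 6 falls in 23 (adjusted p = 0.242), with IRF1 at -5.27 ± 0.184 and USP18 at 2.44 ± 0.465. Unfolded protein response genes gave 6 rises and 7 falls in 24 (adjusted p = 0.176), with ASNS at 2.82 ± 0.178 and XBP1 at -1.70 ± 0.0990, and the list was called down without P0 replicate 2 (adjusted p = 0.0391). PI3K and AKT genes gave 3 rises and 4 falls in 9 (adjusted p = 0.280), with SGK1 at -3.85 ± 0.351.

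Markers of other cell types were mixed. Endothelial markers fell in 3 of 16 cases (median -0.10, adjusted p = 0.0913), namely SELE (at least 13.5-fold), LYVE1 (at least 3.29-fold) and NOS3 (-1.44 ± 0.462). The endothelial list was called down without untreated replicate 1 (median -0.44, adjusted p = 0.0463) or 2 (median -0.34, 0.0396) and with all probe sets (0.0496). Untreated replicates differed, in genes named after their values were seen. CDH5, ECSCR, ICAM2, CLDN5, ERG and EGFL7 lay above every P0 array in replicates 1 and 2. In replicate 3 these same genes lay below every P0 array. The other markers of the list did not show this pattern. PECAM1 changed by -0.84 ± 0.736 (adjusted p = 0.346). Muscle markers gave 2 rises and 1 fall in 9 (adjusted p = 0.280), with cardiac actin ACTC1 up at least 4.14-fold, a bound that rests mostly on untreated replicate 3 (8.78, against 5.82 and 5.30), adipocyte markers 1 fall in 5, PPARG, with both means in the range of the reporter controls (list adjusted p = 0.417), and none of 3 measured lymphocyte markers passed limma's test, with 0 at an unadjusted p under 0.05. The single erythrocyte marker measured, HBB, fell by 0.77 on the log2 scale. Of the fixed panel, FN1 fell by 0.37 (SE 0.112, adjusted p = 0.0138) on its representative probe set with another of its probe sets called in the opposite direction, and it did not pass without untreated replicate 3 (adjusted p = 0.0578). LOX (0.30 ± 0.159, adjusted p = 0.127) and COL3A1 (0.18 ± 0.292, adjusted p = 0.614) did not pass, and the COL3A1 probe set lay at only 5.93 in untreated cells. The median, mean and test of the protease, interferon, PI3K and muscle lists differed in sign.

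In total 5933 probe sets rose and 4550 fell in culture, or 59.4% of those tested, with 2543 rising and 2343 falling at least 2-fold. These held 2531 genes up and 1457 down, while 5180 called probe sets had no single gene symbol. The 2 groups did not overlap at 65.1% of probe sets, where chance gives 10%. Adjusted over the list alone, the counts of each list were the same, except that the collagen list had 2 falls, the TGF-β induced list 13 and the glycolysis list 2. Scan dates are not given in the sources used here, so a batch between P0 and P2 arrays could not be checked for. Of the 105 called genes that the naming rule chose, 102 passed in all 6 fits that left out 1 array; besides FN1, NOS3 did not pass without untreated replicate 3 (adjusted p = 0.0780) and the muscle gene MYH7 not without P0 replicate 2 (0.118).

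**Figure D2:**
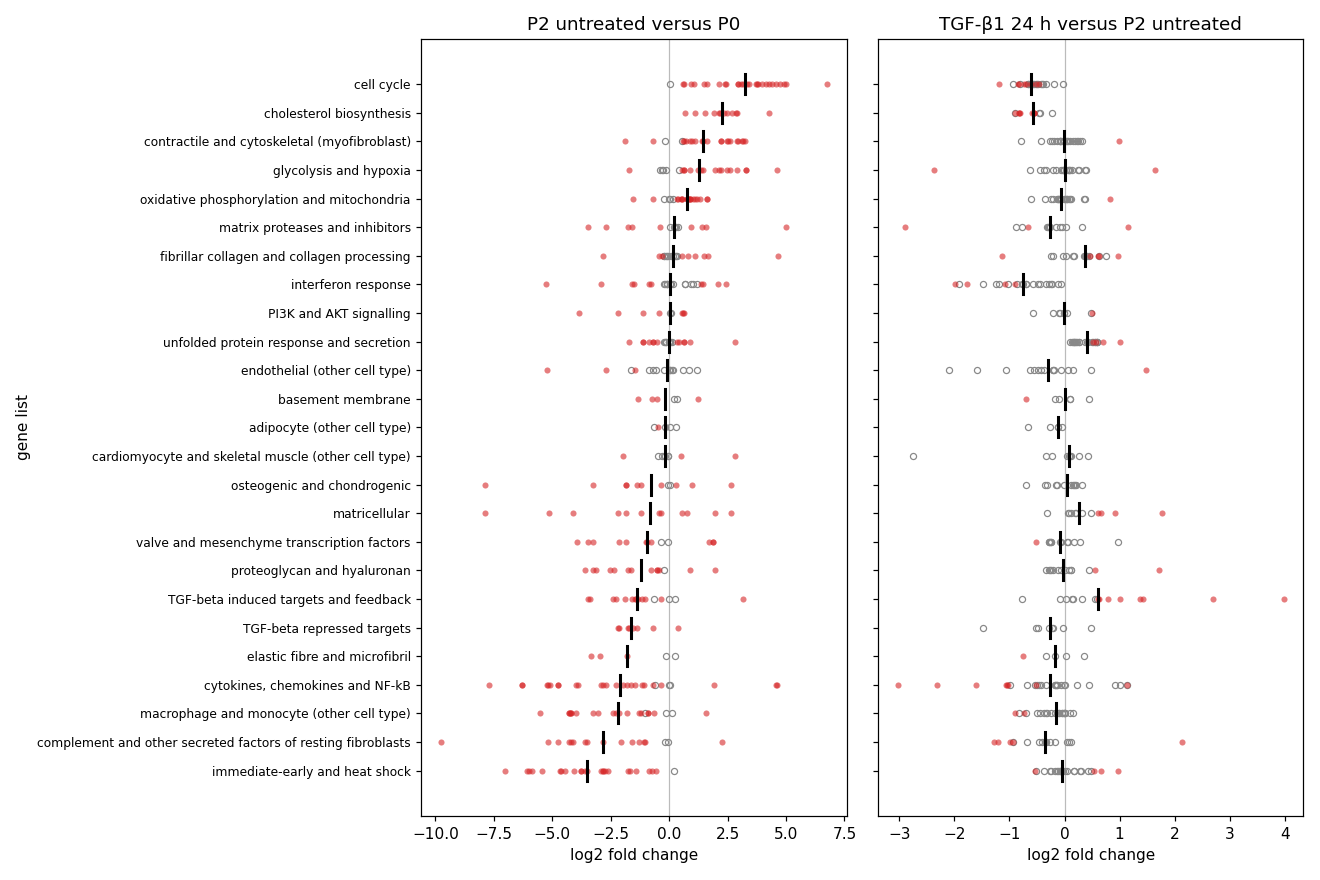
Log2 fold change of each measured member of the gene lists, for P2 untreated against P0 and for TGF-β1 at 24 h against untreated, with red filled points for called genes, grey open points for genes not called, and a black bar at the list median. In culture the median lies at 3.25 for the cell cycle list and at -3.53 for the immediate-early list, and at 24 h of TGF-β1 at -0.60 and -0.04.

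The second comparison asked for the early response of P2 cells to TGF-β1. Within 8 h 5 of 16 TGF-β induced genes had risen, in a list called up (adjusted p = 4.0e-06; adjusted p = 0.0964 with an estimated correlation), and among the largest falls were THBD and VCAM1. PMEPA1, a feedback inhibitor of TGF-β signalling, rose 6.24-fold (log2 fold change 2.64 ± 0.247, adjusted p = 0.000564, 3 against 3 arrays), and the cytokine LIF rose at least 4.44-fold (adjusted p = 0.000491). Tissue factor F3, the starter of coagulation, rose 7.12-fold (2.83 ± 0.424), whereas thrombomodulin THBD, a brake on coagulation, fell at least 4.35-fold.

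Other large rises were in the hormone PTHLH (2.04 ± 0.182), the hyaluronan synthase SHAS2 (1.97 ± 0.191), the neurotrophin BDNF (1.88 ± 0.348), RNF128 (at least 2.88-fold) and the LIM protein CSRP2 (1.68 ± 0.302). Other large falls were in the potassium channel subunit KCNE1 (-1.96 ± 0.370), TMEM100 (at least 1.69-fold), the metabolic kinase PDK4 (-1.71 ± 0.284), ALDH1A1 (-1.62 ± 0.411), FAM26F (-1.61 ± 0.267), GPD1L (-1.58 ± 0.207) and the adhesion molecule VCAM1 (-1.52 ± 0.223). The TMEM100 bound rests mostly on untreated replicate 3 (6.625, against 4.978 and 4.416). Its log2 fold change was -1.82 as deposited and -1.18 without that array.

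In the TGF-β induced list 5 of 16 genes rose and 0 fell, 7 adjusted over the list alone, with a median of 0.43. Besides PMEPA1 and LIF, the transcription factors SNAI1 (1.45 ± 0.225) and BHLHE40 (0.75 ± 0.173) rose. The matricellular list had 2 rises in 12, TNC (0.95 ± 0.129) and THBS2 (0.84 ± 0.196), 3 adjusted over the list alone (adjusted p = 0.0164; adjusted p = 0.149 with an estimated correlation). That call was lost without 8 h replicate 3 (adjusted p = 0.0588), without untreated replicate 2 (0.0777) and in a block fit of the P2 arrays (0.0554). The unfolded protein response list had 3 rises in 24, CREB3L2 (1.19 ± 0.187), MANF (0.76 ± 0.117) and SEC24D (0.53 ± 0.115), 4 adjusted over the list alone (adjusted p = 3.7e-05; adjusted p = 0.622 with an estimated correlation).

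Cholesterol biosynthesis genes were lower as a list, with a median of -0.37 (adjusted p = 2.6e-05; adjusted p = 0.0964 with an estimated correlation). Only FDFT1 (-0.77 ± 0.152) of 12 was called over all probe sets, and 9 passed adjusted over the list alone. Interferon response genes were lower as a list too (median -0.41, adjusted p = 0.00180; adjusted p = 0.759 with an estimated correlation), with 2 of 23 called, also 2 adjusted over the list alone, IRF1 (-1.0 ± 0.184) and STAT2 (-0.56 ± 0.142). That call was lost without 8 h replicate 2 (adjusted p = 0.200, median -0.13) or untreated replicate 3 (0.0658). The median was -0.66 without untreated replicate 2. These fits held no replicate block, so leaving out 1 array also unbalanced the replicate numbers between the 2 groups. With replicate number as a block over all 12 arrays, no list call at 8 h changed. TGF-β repressed genes gave 2 falls in 8, TXNIP (-0.86 ± 0.160) and SMAD3 (-0.82 ± 0.156), and the list was not called (adjusted p = 0.0893). It was called down without 8 h replicate 1 (0.0473) and against random lists (0.00917).

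No change of the contractile list was detected at 8 h: limma called 0 of 23 genes, 0 adjusted over the list alone, and 3 were at an unadjusted p under 0.05, with 2 higher and 1 lower (median 0.05, adjusted p = 0.622). ACTA2 changed by -0.01 ± 0.159, TAGLN by 0.12 ± 0.136 and CNN1 by 0.21 ± 0.125. With number as a block among P2 arrays CDH11 (0.55, adjusted p = 0.00801) passed. Block fits were read only for genes that the naming rule chose, so list members called in them were not counted. In the same comparison 0 of 28 cell cycle genes were called by limma without a block, with 0 at an unadjusted p under 0.05 (list adjusted p = 0.197). In the block fit CDC20 fell (-0.57, adjusted p = 0.0211). The cell cycle list was called down without 8 h replicate 3 (0.0484) or untreated replicate 2 (0.0110) and against random lists (0.0394). Of the collagen list, LOXL1 (0.47 ± 0.110) alone among 19 genes rose. Single called members elsewhere included VEGFA (1.25 ± 0.216) and ADM (-1.40 ± 0.233) of the hypoxia list, IGFBP5 (1.01 ± 0.186) and IGF1 (-0.80 ± 0.154) of the secreted factors, GADD45B (1.08 ± 0.181) of the immediate-early list and PLAU (-1.41 ± 0.293) of the proteases. Endothelial markers had 1 rise in 16, the transcription factor ERG (1.10 ± 0.258), and macrophage markers 1 fall in 22, CD14 (-0.59 ± 0.154). The median, mean and test differed in sign for the collagen, proteoglycan, osteogenic, immediate-early, oxidative phosphorylation, PI3K and endothelial lists. FN1 (0.23 ± 0.112), LOX (0.56 ± 0.159, adjusted p = 0.0717), IL6 (-0.04 ± 0.221), COL3A1 (-0.21 ± 0.292), TOP2A (-0.36 ± 0.198) and PECAM1 (-0.72 ± 0.736) did not pass, though PECAM1 (adjusted p = 0.00614) and LOX (0.00860) did in that block fit.

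At 8 h 447 probe sets rose and 447 fell, or 5.07%, with 118 and 127 at least 2-fold, holding 165 genes up and 171 down. Groups did not overlap at 25.5% of probe sets, against 10% by chance for arrays not linked by replicate number, which these P2 arrays were. With replicate number as a block in a fit of the P2 arrays alone, 1006 rose and 1194 fell, 889 of the original 894 among them. Without the P2 arrays numbered 3, whose endothelial markers lay apart, 116 rose and 149 fell. Leaving out single arrays moved the counts by more than 1.5 times for 5 arrays: 178 up and 186 down without untreated replicate 3, 258 and 256 without untreated replicate 1, and 196 and 195, 261 and 231, and 203 and 255 without 8 h replicates 1, 2 and 3. Of the 43 called genes that the naming rule chose 22 passed in all 6 such fits. Among those that did not, with the highest adjusted p, were ALDH1A1 (0.151 without 8 h replicate 2), STAT2 (0.171 without untreated replicate 3), CD14 (0.170 without 8 h replicate 3), BHLHE40 (0.112 without 8 h replicate 1) and THBS2 (0.115 without untreated replicate 1). So were LOXL1 (0.108) and PLAU (0.0719) without untreated replicate 1, IGF1 (0.0614) and RNF128 (0.102) without untreated replicate 3, KCNE1 (0.0553), ERG (0.104) and SMAD3 (0.0563) without 8 h replicate 1, TMEM100 (0.0973) without 8 h replicate 2, and FDFT1 (0.0587) and SEC24D (0.0868) without 8 h replicate 3. With arrays centred on their median 59.0% of called probe sets were rises, against equal numbers of rises and falls as deposited.

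The third comparison asked for the later response, at 24 h of TGF-β1. LIF rose at least 11.5-fold (adjusted p = 6.33e-06, 3 against 3 arrays), and the matrix glycoprotein tenascin-C, TNC, rose 3.40-fold (1.77 ± 0.129, adjusted p = 3.91e-05). VCAM1 fell 8.19-fold (log2 fold change -3.03 ± 0.223, adjusted p = 3.91e-05), and the vasodilator peptide adrenomedullin, ADM, fell 5.16-fold (-2.37 ± 0.233, adjusted p = 0.000230). As lists, TGF-β induced, matricellular, collagen and unfolded protein response genes were higher, while cholesterol, cell cycle, interferon, cytokine and complement genes were lower. With an estimated correlation only the TGF-β induced, matricellular and cholesterol lists held, each with an adjusted p of 0.0469. Proteoglycan (adjusted p = 0.753), basement membrane (0.831) and elastic fibre genes (0.622) were not called.

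Other large rises were in F3 (3.03 ± 0.424), the fructose transporter SLC2A5 (2.78 ± 0.760, and 1.60 without untreated replicate 3), PMEPA1 (2.70 ± 0.247), BDNF (2.46 ± 0.348), PTHLH (2.40 ± 0.182), the serotonin receptor HTR1D (at least 1.71-fold) and C1QTNF3 (2.19 ± 0.326). Other large falls were in periplakin PPL (-3.53 ± 0.512), KCNE1 (-3.04 ± 0.370), the protease ADAMTS1 (-2.90 ± 0.661), FGL2 (-2.50 ± 0.202), CDO1 (-2.39 ± 0.535) and THBD (at least 4.35-fold). The plot of genes per array shows LIF, PMEPA1, TNC, ASPN, VCAM1 and THBD beside ACTA2 and TPM1.

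**Figure D3:**
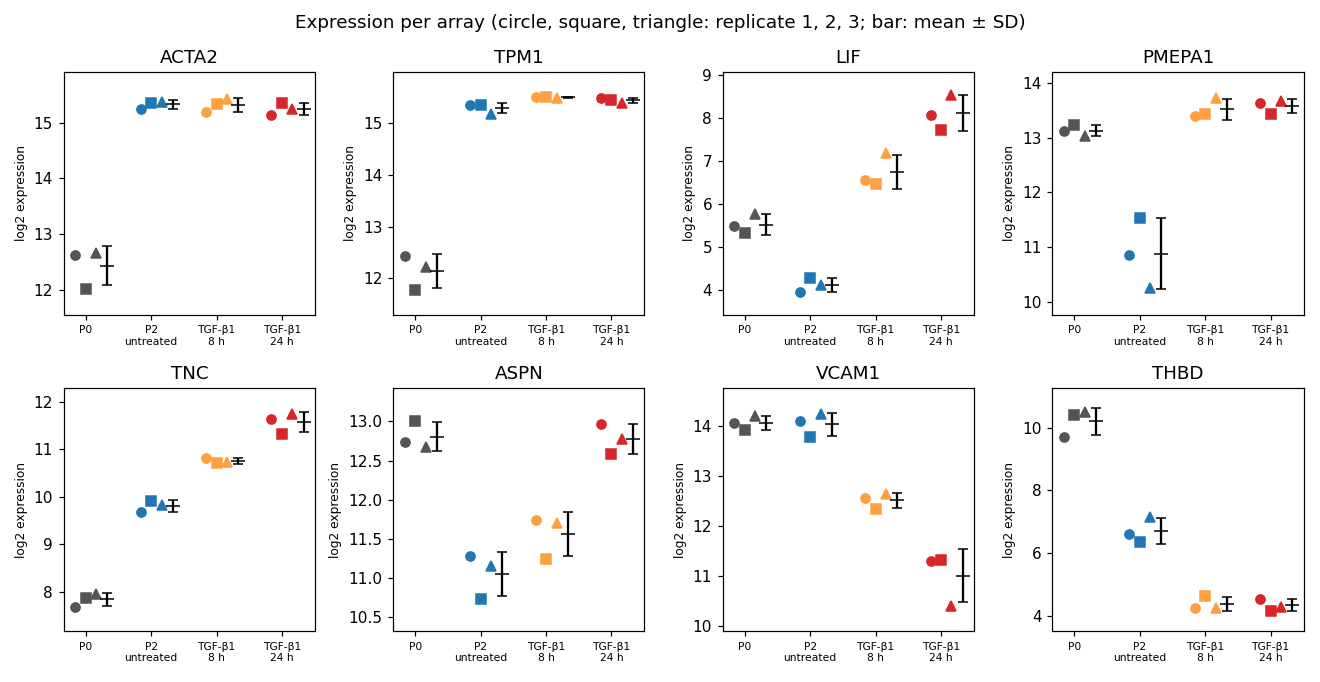
Log2 expression of 8 genes in each of the 12 arrays, by group, with the mean and SD and a circle, square or triangle for replicates 1, 2 and 3. Mean LIF lies at 4.11 in untreated cells, 6.74 at 8 h and 8.10 at 24 h, while mean ACTA2 lies at 15.33, 15.32 and 15.25.

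In the TGF-β induced list 8 of 16 genes rose and 0 fell, 10 adjusted over the list alone, with a median of 0.60 (adjusted p = 2.0e-07; adjusted p = 0.0469 with an estimated correlation). SNAI1 (1.43 ± 0.225) and TGFB1 (1.38 ± 0.249), the gene of the cytokine itself, rose with LIF and PMEPA1, as did FN1 (0.61 ± 0.112, adjusted p = 0.00654). In the matricellular list 4 of 12 rose, also 4 adjusted over the list alone (median 0.26, adjusted p = 0.000865; adjusted p = 0.0469 with an estimated correlation), namely TNC, THBS2 (0.91 ± 0.196), THBS1 (0.66 ± 0.159) and FN1; that median was 0.43 without untreated replicate 3. Fibrillar collagen and processing genes rose in 4 of 19 cases and fell in 1, with 8 and 1 adjusted over the list alone (median 0.37, adjusted p = 0.00232; adjusted p = 0.253 with an estimated correlation). COL5A1 (0.97 ± 0.166), COL8A1 (0.63 ± 0.153) and the cross-linking enzyme LOX (0.60 ± 0.159) rose, whereas COL3A1 fell (-1.14 ± 0.292, adjusted p = 0.0329) from a low mean of 5.93 on its only named probe set. Unfolded protein response genes rose in 4 of 24 cases, 12 adjusted over the list alone (median 0.41, adjusted p = 5.0e-08; adjusted p = 0.253 with an estimated correlation), among them CREB3L2 (1.01 ± 0.187), MANF (0.70 ± 0.117) and KDELR2 (0.52 ± 0.115).

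Cholesterol biosynthesis genes fell in 8 of 12 cases, 10 adjusted over the list alone (median -0.57, adjusted p = 5.0e-08; adjusted p = 0.0469 with an estimated correlation). ACAT2 (-0.90 ± 0.127), FDPS (-0.83 ± 0.103), HMGCS1 (-0.83 ± 0.196) and FDFT1 (-0.81 ± 0.152) changed most. Cell cycle genes fell in 8 of 28 cases, 19 adjusted over the list alone (median -0.60, adjusted p = 7.5e-09; adjusted p = 0.335 with an estimated correlation), including thymidylate synthase TYMS (-1.20 ± 0.232), CCNB2 (-0.84 ± 0.188), TOP2A (-0.84 ± 0.198) and PTTG1 (-0.75 ± 0.210). Interferon response genes fell in 4 of 23 cases, 10 adjusted over the list alone (median -0.76, adjusted p = 8.3e-06; adjusted p = 0.480 with an estimated correlation), with GBP1 at -1.99 ± 0.293, RSAD2 at -1.77 ± 0.431, the immunoproteasome subunit PSMB8 at -1.07 ± 0.303 and IRF1 at -0.90 ± 0.184. The interferon median ranged from -0.45 without 24 h replicate 2 to -1.04 without untreated replicate 2.

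Cytokine and NF-kB genes fell in 7 of 28 cases and rose in 1, with 10 and 3 adjusted over the list alone (median -0.26, adjusted p = 0.00754; adjusted p = 0.138 with an estimated correlation). VCAM1, AMCF-II (-2.32 ± 0.265), SOD2 (-1.61 ± 0.205) and IL6 (-1.05 ± 0.221, adjusted p = 0.0124) fell, and the adhesion molecule ICAM1 rose (1.13 ± 0.230). The list call was lost without untreated replicate 2 (adjusted p = 0.0757), and its median was -0.41 without untreated replicate 3. Complement and other secreted factors fell in 4 of 17 cases and rose in 1, with 5 and 1 adjusted over the list alone (median -0.36, adjusted p = 0.0188; adjusted p = 0.438 with an estimated correlation). C1S (-1.28 ± 0.203), C1R (-1.21 ± 0.228) and C7 (-0.98 ± 0.269; adjusted p = 0.0595 in the block fit of P2 arrays) fell, and IGFBP5 rose (2.13 ± 0.186). That list call was lost without 24 h replicate 2 (adjusted p = 0.0823), without untreated replicate 3 (0.0943, median -0.18) and without the P2 arrays numbered 3 (0.0629), and the median was -0.60 without untreated replicate 2. Macrophage markers fell in 2 of 22 cases, SLA-DMA (-0.90 ± 0.167) and CD14 (-0.73 ± 0.154), and the list was not called (adjusted p = 0.104). With replicate number as a block it was (0.00936), as it was without 24 h replicate 2 (0.00507) or untreated replicate 1 (0.0485) or 3 (0.0144).

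The contractile list was again not called, and 1 of 23 genes passed, also 1 adjusted over the list alone (median -0.01, mean 0.01, adjusted p = 0.831). The fry test for changes in either direction gave an adjusted p of 0.0153. That gene was the adhesion molecule CDH11 (1.00 ± 0.227, adjusted p = 0.0190), which did not pass without untreated replicate 3 (adjusted p = 0.0824). ACTA2 (-0.08 ± 0.159), TAGLN (0.06 ± 0.136) and CNN1 (0.24 ± 0.125, adjusted p = 0.289) did not pass. Elsewhere the proteoglycans ASPN (1.71 ± 0.182) and BGN (0.56 ± 0.104) rose, 2 of 14 in their list. The hyaluronan synthase SHAS2 was not among the measured members of that list. Its mean was 6.97 in untreated cells, 8.93 at 8 h and 9.12 at 24 h. The protease FAP rose (1.15 ± 0.218), and ADAMTS1 and SERPINE2 (-0.66 ± 0.177) fell, in a list of 14 that was not called (adjusted p = 0.131). That list was called down in the block fit of P2 arrays (0.0478), with all probe sets (0.0285) and against random lists (0.00111). VEGFA rose (1.64 ± 0.216), and ERG (1.49 ± 0.258) was the only endothelial marker of 16 called in this fit, in a list that was not (adjusted p = 0.654). Without the P2 arrays numbered 3 the endothelial list was called down (adjusted p = 0.0168). PECAM1 changed by -1.60 ± 0.736 (adjusted p = 0.223) in the fit without pairing, and with replicate number as a block among P2 arrays it fell (adjusted p = 0.000180). The median, mean and test differed in sign for the contractile, proteoglycan, osteogenic, immediate-early, PI3K, glycolysis and muscle lists.

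At 24 h 754 probe sets rose and 744 fell, or 8.49%, with 208 and 266 at least 2-fold, holding 266 genes up and 341 down. Groups did not overlap at 25.3% of probe sets, against 10% by chance for arrays not linked by replicate number. With replicate number as a block among the P2 arrays alone, 1723 rose and 1796 fell, including 1494 of the original 1498. Without the P2 arrays numbered 3, 314 rose and 448 fell. Counts moved by more than 1.5 times without untreated replicate 3 (394 up and 406 down), untreated replicate 1 (472 and 446) and, for rises, 24 h replicate 1 (458). Of the 68 called genes that the naming rule chose, 41 passed in all 6 fits that left out 1 array. Among those that did not, with the highest adjusted p, were LOX (0.154), COL8A1 (0.104), THBS1 (0.0960), COL3A1 (0.133), TOP2A (0.0975), C7 (0.165), RSAD2 (0.101), SERPINE2 (0.153) and KDELR2 (0.0710), each without untreated replicate 3. Others were SLC2A5 (0.122), PTTG1 (0.160) and CCNB2 (0.0721) without 24 h replicate 1, ADAMTS1 (0.0661) and CDO1 (0.0641) without 24 h replicate 2, and PSMB8 (0.167), HMGCS1 (0.0804), THBS2 (0.0626), CD14 (0.0561) and IL6 (0.0544) without untreated replicate 1.

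The fourth comparison tested the difference between the 2 times of TGF-β1 exposure. In the fit without replicate number few genes separated 24 h from 8 h, while a block fit of the P2 arrays called 430 probe sets. In the first of these fits LIF rose further, and HTR1D rose from a mean at background. The proteoglycan ASPN rose 2.31-fold (log2 fold change 1.21 ± 0.182, adjusted p = 0.0251, 3 against 3 arrays), and VCAM1 fell another 2.85-fold (log2 fold change -1.51 ± 0.223, adjusted p = 0.0231). In total 25 probe sets were higher at 24 h and 16 lower, holding 9 named genes up and 8 down, and 1635 probe sets were at an unadjusted p under 0.05. The 2 times did not overlap at 13.7% of probe sets, against 10% by chance for arrays not linked by replicate number.

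The other genes higher at 24 h were IGFBP5 (1.12 ± 0.186), the potassium channel KCNMA1 (0.97 ± 0.170), the phosphodiesterase PDE3A (0.95 ± 0.113), the procollagen processing enhancer PCOLCE2 (0.92 ± 0.156), NR4A3 (0.86 ± 0.143) and TNC (0.82 ± 0.129). LIF differed by 1.37 ± 0.232 and HTR1D by at least 1.71-fold. Those lower at 24 h were CLDN11 (-1.75 ± 0.279), FGL2 (-1.56 ± 0.202), angiogenin ANG (-1.38 ± 0.161), the chemokine CXCL16 (-1.21 ± 0.167), PEG10 (-1.14 ± 0.129), FGF12 (-1.10 ± 0.192) and the immunoproteasome subunit PSMB10 (-0.65 ± 0.110). Of these 17 genes PEG10 alone passed in all 6 fits that left out 1 array, and ANG, FGL2 and PDE3A failed only without 8 h replicate 1 (adjusted p = 0.0628, 0.0720 and 0.0628). The highest adjusted p came without 8 h replicate 1 for VCAM1 (0.118), LIF (0.197), HTR1D (0.118), IGFBP5 (0.152), NR4A3 (0.147), KCNMA1 (0.193) and PSMB10 (0.203). It came without 24 h replicate 1 for ASPN (0.113), TNC (0.137), PCOLCE2 (0.155), CXCL16 (0.0734), CLDN11 (0.141) and FGF12 (0.168).

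As lists, cell cycle genes were lower at 24 h than at 8 h (median -0.43, adjusted p = 1.2e-12; adjusted p = 0.262 with an estimated correlation). Of 28 members limma called 0, with 11 falls adjusted over the list alone and 13 at an unadjusted p under 0.05, among them PTTG1 (-0.73 ± 0.210). Cholesterol (median -0.18, adjusted p = 0.000991), cytokine (-0.14, 0.00299) and interferon genes (-0.29, 0.0184) were also lower as lists. Collagen (median 0.26, adjusted p = 0.000991), matricellular (0.12, 0.0190), unfolded protein response (0.14, 0.0128) and TGF-β induced genes (0.05, 0.0281) were higher. With an estimated correlation these 7 had adjusted p = 0.189, 0.189, 0.767, 0.243, 0.189, 0.767 and 0.361, so none held. Single arrays ended calls too. The TGF-β induced call was lost without 24 h replicate 1 (0.0884, median 0.02) or 2 (0.0695, median 0.13) or 8 h replicate 2 (0.0570). The unfolded protein response call was lost without 24 h replicate 2 (0.242) or 8 h replicate 1 (0.197, median 0.085). The matricellular call was lost without 24 h replicate 2 (0.0601, median 0.155) or 8 h replicate 2 (0.185, median 0.06). The same held for interferon without 24 h replicate 2 (0.724, median -0.02) or 8 h replicate 1 (0.270) or 3 (0.234), and for cytokines without 8 h replicate 2 (0.158). Against random lists TGF-β induced genes had 0.289. Among the lists that kept their calls, the collagen median fell to 0.15 without 24 h replicate 3. Adjusted over the list alone, 2 cholesterol and 5 cytokine genes fell, and 2 matricellular and 2 TGF-β induced genes rose, VCAM1, TNC and LIF among those called over all probe sets. Without a block limma called 0 of 12 cholesterol, 0 of 23 interferon, 0 of 19 collagen and 0 of 24 unfolded protein response genes, with 3, 2, 8 and 1 at an unadjusted p under 0.05. In the block fit of P2 arrays, read only for genes that the naming rule chose, the cholesterol genes ACAT2 (-0.55, adjusted p = 0.0293) and FDPS (-0.54, 0.0229) fell. The interferon genes GBP1 (-1.08, 0.018) and PSMB8 (-0.67, 0.0289) fell in that fit too. ACTA2 (-0.07 ± 0.159), TAGLN (-0.06 ± 0.136), CNN1 (0.03 ± 0.125), FN1 (0.38 ± 0.112), LOX (0.04 ± 0.159), IL6 (-1.01 ± 0.221, adjusted p = 0.111), COL3A1 (-0.93 ± 0.292), TOP2A (-0.47 ± 0.198) and PECAM1 (-0.88 ± 0.736) did not pass, though PECAM1 (adjusted p = 0.0109) and COL3A1 (0.0213) did with number as a block among P2 arrays.

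In fits without a replicate block, the number of calls in this comparison depended on single arrays. Without 8 h replicate 1 only 2 probe sets rose and 2 fell, without 8 h replicate 3 it was 6 and 5, without 24 h replicate 1 it was 6 and 7, without 8 h replicate 2 it was 10 and 9, and without 24 h replicate 3 it was 13 and 15. With replicate number as a block 48 rose and 61 fell, and among the P2 arrays alone 198 and 232, all 41 original probe sets included both times. The share of rises was 61.0% as deposited and 45.1% with arrays centred on their median.

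Responses at the 2 times were related, as the plot of 8 h against 24 h changes shows. Across 17638 probe sets, which are not independent replicates, the log2 fold changes correlated at r = 0.788, where unchanged groups of independent arrays sharing the untreated ones gave 0.501 in simulation. The covariance was 0.105, against 0.0191 in simulation. Of the called probe sets 325 rose at both times, 281 fell at both and 0 moved in opposite directions, which the shared untreated arrays favour. The culture response and the TGF-β1 responses correlated at 0.0171 (8 h) and 0.00958 (24 h), where unchanged groups of independent arrays gave -0.5 in simulation, as the untreated arrays enter with opposite signs. The covariances were 0.00674 and 0.00463, against -0.0191 in simulation for both, which leaves out the link between P2 arrays of the same number. The culture response against the 24 h minus 8 h difference, which share no arrays, gave r = -0.00706.

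**Figure D4:**
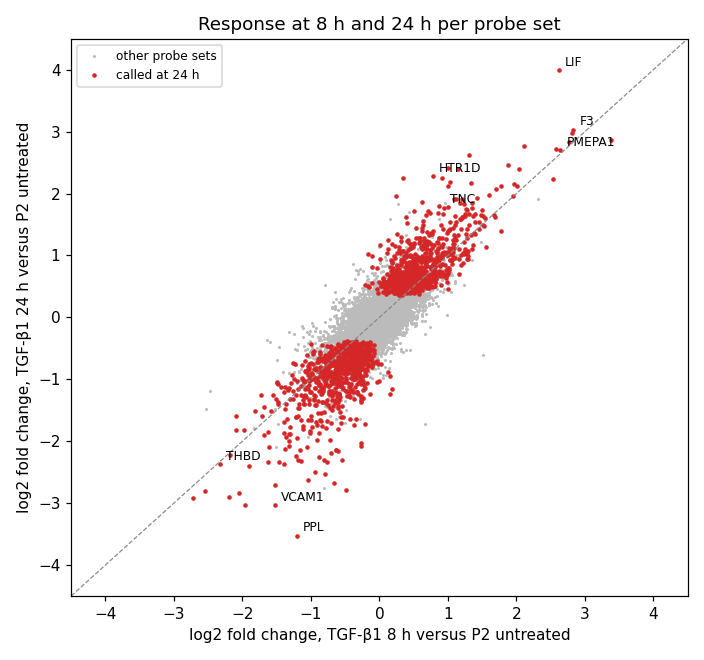
Log2 fold change against untreated cells at 8 h (horizontal) and 24 h (vertical) of TGF-β1, 1 point per probe set, with probe sets called at 24 h in red and a dashed line of equal change. TNC lies above the line at 0.95 and 1.77, and VCAM1 below it at -1.52 and -3.03.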

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

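The tests on endothelial cells, array brightness, precision, leukocytes, digest stress and interstitial share below, and the fits with a P2 block or without arrays numbered 3, were chosen after the result was seen; the test on bright probe sets and the splits of the arrays were planned.

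The difference between 24 h and 8 h of TGF-β1 was tested directly, and 17 named genes and 8 gene lists passed. With an estimated correlation none of the 8 lists passed (adjusted p from 0.189 to 0.767), and 16 of the 17 genes lost their call without some array, all but PEG10. Both checks used fits without replicate number, so differences shared by same-number P2 arrays stayed in them. Neither check was run on a block fit. Of the genes, LIF (log2 difference 1.37), ASPN (1.21), IGFBP5 (1.12), KCNMA1 (0.97), PDE3A (0.95), PCOLCE2 (0.92), NR4A3 (0.86) and TNC (0.82) were higher at 24 h, as was HTR1D by at least 0.77 (1.495 as deposited, from a mean at background). CLDN11 (-1.75), FGL2 (-1.56), VCAM1 (-1.51), ANG (-1.38), CXCL16 (-1.21), PEG10 (-1.14), FGF12 (-1.10) and PSMB10 (-0.65) were lower. Among lists, the medians were 0.26 for collagen, 0.14 for unfolded protein response, 0.12 for matricellular and 0.048 for TGF-β induced genes, and -0.43 for cell cycle, -0.29 for interferon, -0.18 for cholesterol and -0.14 for cytokine genes. The macrophage list was not called (adjusted p = 0.127) but was with replicate number as a block (0.00654). In the block fit of P2 arrays both the macrophage (0.00361) and the endothelial list (0.00598) were called down, as was the complement list (0.0497), while the matricellular (0.0553) and TGF-β induced lists (0.0672) lost their calls.

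Signal also appeared in the reporter control probe sets, which no comparison uses. Of these control probe sets, 11 lay over log2 4 in at least 3 arrays, and the brightest had a mean of 15.26 over the 12 arrays. No explanation of this signal was tested.

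Endothelial markers lay lower in the P2 arrays numbered 3 than in the other P2 arrays, by a median of 1.43 on the log2 scale. Of the 16 markers 81.2% were lower in all 3 P2 groups, against 23% of all tested probe sets. The 3 P2 groups are linked by replicate number, so they are not independent of each other. The median over all tested probe sets differed by 0.0123, but the deposited values share their array medians by normalization, so this decides nothing about dim arrays. Fewer endothelial cells in the cultures numbered 3 may explain the pattern: 10 of the 16 markers lay over log2 4 in all 9 P2 arrays and none is in another list, with CDH5 at 10.79 in untreated replicate 2 and 6.72 in replicate 3. Macrophage markers were lower in 77.3% of cases too, but by a median of only 0.24, while 75% of cell cycle, 66.7% of osteogenic, 65.2% of interferon and all 5 elastic fibre genes were higher. Donor or culture differences between replicate numbers stay open, untested.

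Contractile genes were not called as a list with TGF-β1. Bright probe sets near the top of the scale would hide a rise, yet the 12 members under log2 12 in untreated cells had a median 24 h change of 0.0119 (SE 0.119), and the 11 brighter ones -0.02. Low precision would also hide a rise, but for 95.7% of the 23 members (22) the upper bound of the change lay under a 2-fold rise. For the 11 brighter members, such as ACTA2 at 15.33 in untreated cells, that bound limits only the measured change. Neither test therefore excludes a hidden rise of these brighter members. Smaller changes stay open, as does a ceiling in cells already activated by plastic, which was not tested.

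Macrophage and immediate-early genes lay lower in P2 untreated cells than in P0 cells. Leukocytes in the fresh digest may explain the macrophage part, with a list median of -2.2 and 81.8% of 22 markers called down; among the most abundant, C1QC read 12.37 in P0 and 8.39 in P2, SLA-DRB1 11.72 and 7.45, and CTSS 11.35 and 10.43. None of the 22 is in another list, but 19 lay over log2 4 in all 9 P2 arrays, so the cultured cells show signal for them too. A lower share of interstitial cells in the digest would raise all other cell types alike, while endothelial and macrophage medians differed by 2.1 (SE over genes 0.553). That does not decide the question, because the difference also depends on the endothelial signal of the P2 cultures. CDH5 read 9.96, 10.79 and 6.72 in untreated replicates 1, 2 and 3, against 7.93 to 8.00 in P0 arrays. Stress of the enzymatic digest and culture cannot be told apart for the immediate-early list (median -3.53), because all P0 arrays are fresh digests.

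For each comparison the 6 arrays make 10 splits, too few for a share under 0.05, and 1 of 10, the real one, gave as many calls. The real splits called 10483, 894, 1498 and 41 probe sets by limma, and the highest other split called 0 in each, with 688, 1378, 1855 and 2329 probe sets at an unadjusted p under 0.05 against 11138, 3067, 4004 and 1635. For 24 h against 8 h a split that parts fewer replicate numbers thus exceeded the real unadjusted count, which points to structure by replicate number. Among splits that part all replicate numbers, as the real one does, the highest unadjusted count was 336. With number as a block 48 probe sets were higher and 61 lower, and 198 and 232 among P2 arrays alone.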

How the results depend on the processing

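The block fit of P2 arrays, the fit without P2 arrays numbered 3 and the comparison of culture with the 24 h minus 8 h difference were chosen after seeing the data. No gene that the naming rule chose reversed a call under the alternatives run, and calls per direction in culture stayed within 1.5 times of 5933 and 4550 except against a 1.5-fold change (2599 up, 2219 down). Where calls changed, the cause was not tested, except that fits with fewer arrays have less precision. A test against a 1.5-fold change also asks for more. Fits that left out 1 P2 array held no replicate block, so they also left the linked replicate numbers unbalanced between P2 groups. Quantile normalization, a floor at log2 4 and a filter at log2 6 moved no probe set count by over 1.5 times. Against a 1.5-fold change 10 rose and 7 fell at 8 h, 59 and 63 at 24 h, all at least 2-fold (10, 7, 59 and 63), and limma called 0 and 0 between the times (0 and 0 at least 2-fold; 76 at an unadjusted p under 0.05). With only the 2 groups fitted it was 264 and 255 at 8 h (83 falls at least 2-fold), 306 and 325 at 24 h, and 0 and 0 between the times (0 and 0 at least 2-fold; 1532 unadjusted). Array weights gave 701 and 762, 1151 and 1123, and 143 and 104 (30 and 36 at least 2-fold). A replicate block gave 1128 falls at 24 h, and 48 and 61 between the times (34 falls at least 2-fold). The block of P2 arrays gave 1006 and 1194, 1723 and 1796, and 198 and 232 (29 and 49 at least 2-fold), with 2 lists up and 7 down between the times. Without P2 arrays numbered 3 it was 116 and 149 (55 rises at least 2-fold), 314 and 448, and 3 and 9 (3 and 9 at least 2-fold). Between the times, no filter gave 15 and 10, median centring 28 falls (24 at least 2-fold), and trend with robust eBayes 39 and 33 (25 falls at least 2-fold). With an estimated correlation 0 lists were up and 2 down in culture, 0 and 0 at 8 h, 2 and 1 at 24 h, and 0 and 0 between the times. Against random lists 5 were down at 8 h and 7 between the times.

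Leaving out 1 array, rises ranged from 5427 to 5640 and falls from 4150 to 4279 in culture. They ranged from 178 to 352 and 186 to 350 at 8 h (72 to 140 and 75 to 157 at least 2-fold), lowest without untreated replicate 3 and highest without untreated replicate 2. At 24 h they ran from 394 to 672 and 406 to 721, and between the times from 2 to 30 and 2 to 15 (2 to 16 and 2 to 14 at least 2-fold), lowest without 8 h replicate 1. Lists down at 8 h ranged from 1 to 3, lowest without 8 h replicate 2, and lists up between the times from 1 to 4, lowest without 24 h replicate 2. The correlation of 8 h and 24 h responses stayed between 0.772 and 0.829. Values near 0 changed sign: culture against 8 h was -0.0103 and -0.0316 without untreated replicates 2 and 3 (highest 0.00585), culture against 24 h -0.0188 and -0.0275 (highest 0.00500), and culture against the 24 h minus 8 h difference 0.000133 without untreated replicate 1 (lowest -0.0185). Signal over background limits low values: 69.2% to 72.1% of probe sets per array lay over log2 4.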

Other observations

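The comparison of TGF-β targets with fresh cells below was chosen after the result was seen, as were the genes named with it.

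PRRX1, a mesenchymal homeobox factor, fell at 8 h (-0.55 ± 0.116) and 24 h (-0.52 ± 0.116), but did not pass without untreated replicate 3 (adjusted p = 0.0919 and 0.0768). CYCS, cytochrome c, rose at both times (0.77 ± 0.167 and 0.82 ± 0.167) as the only called member of 24 oxidative phosphorylation genes, with an adjusted p of 0.0950 at 8 h without untreated replicate 3. The TGF-β receptor gene TGFBR1 rose at both times too (0.63 ± 0.129 and 0.62 ± 0.129). At 24 h the stress genes BTG2 (0.66 ± 0.172) and PPP1R15A (0.53 ± 0.137) rose and JUN fell (-0.54 ± 0.147), and FOXO1 rose (0.49 ± 0.134). LAMB2 (-0.71 ± 0.163) of the basement membrane and FBLN1 (-0.76 ± 0.183) of the elastic fibre fell at 24 h. Leaving out untreated replicate 3 ended the 24 h calls of BTG2 (adjusted p = 0.146), PPP1R15A (0.136), FOXO1 (0.145) and LAMB2 (0.0842), leaving out 24 h replicate 2 that of JUN (0.115), and leaving out untreated replicate 1 that of FBLN1 (0.0957).

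In culture 75% of the 16 TGF-β induced genes were called down, in a list not called with an estimated correlation (adjusted p = 0.103). That passaged cells lost expression driven by TGF-β in the valve is a hypothesis prompted by this share, which is therefore no test of it. Lost signalling would also raise TGF-β repressed genes, but 7 of 8 fell, with a mean of -1.38 (SE 0.301). That list was not called at 24 h of TGF-β1 (median -0.26, adjusted p = 0.131). Without a block limma called 0 of 8, with 4 at an unadjusted p under 0.05, 1 of them higher. With replicate number as a block among P2 arrays, read only for genes that the naming rule chose, ID1 (-1.48, adjusted p = 0.0025) and TXNIP (-0.52, 0.0142) fell at 24 h. At 8 h the list was not called (adjusted p = 0.0893), though it was against random lists (0.00917). As its response to TGF-β1 depended on the fit, the list does not decide the question. Of the 16 genes, 5 both fell in culture and rose at 24 h of TGF-β1. At 24 h, 8 of the 16 still lay below fresh cells and 4 above, with a median of -0.46. PMEPA1 fell in culture (-2.25) and at 24 h of TGF-β1 lay at 0.45 ± 0.247 against P0 (adjusted p = 0.133), whereas BHLHE40 stayed lower (-2.61 ± 0.173) and LIF ended higher (2.59 ± 0.232). The untreated arrays enter both differences with opposite signs, and stress of the digest was not separated from culture, so what lowered the induced genes stays open.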
